A study of Mus musculus with 12 samples.

How the data were processed

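RNA from the skin epidermis of newborn mice was sequenced in 12 libraries, 1 per mouse by the stated design, in 4 genotype groups of 3. Controls carried K14-Cre, a transgene that expresses Cre recombinase in basal keratinocytes. Llgl cKO mice lacked Llgl1 and Llgl2 conditionally, Trp53 het mice had lost a single Trp53 allele conditionally, and Llgl cKO Trp53 het mice combined both. Per the labels, total RNA was made into stranded mRNA libraries. The authors named STAR, featureCounts 1.6.4 and DESeq2 2.11.40.8 with the mouse genome GRCm38. Annotation release, strand setting and filters were not stated. The deposited table held raw counts per gene and library, with no normalization: whole numbers for 46078 genes, whose column totals ran from 6738720 to 14509507. Symbols and positions came from the table and from a GRCm38 annotation, which matched 45229 of the identifiers and 14532 of those tested. No column of the table was left unused, and 214 symbols were shared by several identifiers.

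Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr over the 4 groups (minimum count 10), and 14582 genes were tested. A single quasi-likelihood model with robust estimation was fitted to the 12 libraries, with group means only and 8 residual degrees of freedom. The p-values therefore measure the spread between mice. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. Adjusted p-values are from edgeR unless another tool is named. The square root of the common dispersion, the biological coefficient of variation, was 23.8%. Levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3. Where a gene had 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3, the ratio of summed counts is given with its exact 95% binomial interval. These intervals and floors cover counting error only, since counts were summed over libraries and the spread between mice was left out. Reads were also not counted as unique molecules.

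The 5 pairwise comparisons, the interaction, and the average Llgl and Trp53 effects (6 against 6 libraries) were set before the data were examined, as were the tests, the gene lists, the rule for named genes and most of the alternatives. Named genes were Llgl1, Llgl2 and Trp53, with further genes by rule. In each comparison these were the 5 called genes with the largest positive and the 5 with the largest negative log2 fold change that had a mean of at least 1 CPM in a compared group and a symbol other than a predicted or clone name, without overlap between groups in pairwise comparisons. Added to these were the 2 members with the smallest p of the p53 target list and of each list with at least 2 called members (at least 3 in the Llgl cKO Trp53 het comparison with Trp53 het and in the comparisons of Trp53 genotypes and the interaction). In the average Llgl effect Wnt10b, Nkd1, Serpinb2 and Col1a1 were named outside the rule, after their values were seen, and were not run under the alternatives. The sebaceous gland list in that effect is given by its mean, where the other lists are given by their medians. Other genes singled out beyond that rule are identified in the text as chosen after their values were seen.

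Gene lists, 46 in number with 776 genes of which 773 were in the table, covered epidermal layers, skin appendages, junctions and polarity, the cell cycle, p53 and other signalling targets, stress, metabolism, other cell types and RNA quality. The 40 lists with at least 3 tested members, sex lists aside, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the 40 lists. Each test was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes. Across the 8 comparisons 73 list tests passed with the preset correlation, 0 with an estimated correlation, and 10 by fry. Members called are counted over all genes and, separately, adjusted over the list alone.

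Alternatives were DESeq2 1.42.0, median-of-ratios and upper-quartile scaling, no low-count filter, at least 1 CPM in 3 libraries, a minimum 2-fold change, only the groups compared, sex as a term, replicate number as a block, and each library left out in turn. After the data had been examined, the counts were also taken without control 3 and Trp53 het 3, which stood apart, and without the library of each Trp53 heterozygous group that carried the most Trp53. The latter, Trp53 het 3 and Llgl cKO Trp53 het 1, were the only female libraries of their groups, so that fit left both groups all male. The labels gave no batch or pairing. Replicates with the same number in control and Trp53 het had correlated deviations from their group means (0.62, 0.21 and 0.82 across genes), above 0.1 in each case, although control 1 and Trp53 het 2, with different numbers, gave 0.46. With the replicate block, a single effect shared by all 4 groups, 0 genes were called between control and Trp53 het, as without it. Genes with an unadjusted p below 0.05 went from 63 to 75, where chance gives 729. Same-numbered Llgl cKO and Llgl cKO Trp53 het libraries did not share such an effect (-0.17, -0.35 and 0.030). The block is therefore not a paired test of control and Trp53 het alone, and its 0 calls do not settle the matter. Sex was read from X- and Y-linked transcripts, which gave 7 male and 5 female libraries, with both sexes in each group. Control held 1 male and 2 females, and each other group 2 males and 1 female. The females were control 2, control 3, Llgl cKO 1, Trp53 het 3 and Llgl cKO Trp53 het 1. Control 1 thus shared its sex with Trp53 het 1 and Trp53 het 2, and control 3 with Trp53 het 3. The correlations above therefore do not separate number from sex. Control 2 and Trp53 het 3, both female, gave -0.26.

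The steps were tested on simulated counts with the estimated dispersions, in which 100 of 14353 genes were changed 2-fold and 100 others 4-fold in the Llgl groups. With 3 libraries against 3 the fit recovered 50% and 82% of these for Llgl cKO against control and 55% and 83% for Llgl cKO Trp53 het against Trp53 het. The average effect recovered 79% and 94%. Between 5 and 12 unchanged genes were called in these comparisons, and 0 between control and Trp53 het, where nothing had been changed. Camera called 0 of 40 unchanged lists. The simulated genes varied independently of each other, and the libraries differed only in depth and in the changes set. The simulation therefore does not test camera where genes are correlated, and the recovery rates hold for such counts only.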

Results

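Polyadenylated RNA of newborn mouse epidermis was counted in 12 libraries: 3 control, 3 Llgl cKO, 3 Trp53 het and 3 Llgl cKO Trp53 het. Llgl1 and Llgl2 are mammalian homologues of the Drosophila polarity gene and tumour suppressor lethal giant larvae, and Trp53 encodes the p53 tumour suppressor. Control libraries 1 to 3 held 6738720, 11692573 and 11739107 counts. The Llgl cKO libraries held 14509507, 12669587 and 11681341 counts. Trp53 het libraries held 11696252, 6901424 and 12479062 counts, and Llgl cKO Trp53 het libraries 12035408, 12742531 and 11804019. The first principal component of log2 CPM carried 44.6% of the variance and the second 19.3%.

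Llgl2 transcript was strongly reduced in both Llgl cKO groups. The level of Llgl2 (ENSMUSG00000020782, chromosome 11, 115824049 to 115855780, GRCm38) was 86.7 ± 22.3 CPM in control, 8.35 ± 1.16 in Llgl cKO, 90.9 ± 22.0 in Trp53 het and 8.51 ± 3.38 in Llgl cKO Trp53 het (SD, n = 3). It fell by 3.40 on the log2 scale in the average Llgl effect (adjusted p = 9.5e-06). Llgl1 (ENSMUSG00000020536, chromosome 11, 60699723 to 60714186) was higher, not lower, in the Llgl cKO groups, at 256 ± 33.1 and 215 ± 30.5 CPM against 138 ± 30.6 in control and 133 ± 9.58 in Trp53 het. Its average log2 change of 0.79 was called (adjusted p = 0.0072). The pairwise changes of 0.89, 0.64 and 0.69 were not (adjusted p 0.082, 0.10 and 0.072). Gene counts do not resolve the floxed exons, so the Llgl1 level does not measure recombination. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was at 121 ± 10.98 CPM in control and 118 ± 5.50 in Llgl cKO, against 79.2 ± 30.9 in Trp53 het and 77.3 ± 18.2 in Llgl cKO Trp53 het. The average Trp53 effect on Trp53 was -0.61 on the log2 scale (95% interval -0.99 to -0.23) and was not called (adjusted p = 1). The library labelled Trp53 het 3 had 115 CPM of Trp53, within the control range, against 61.8 and 60.9 in Trp53 het 1 and 2. Llgl cKO Trp53 het 1 was also higher than the rest of its group, at 98.3 CPM against 67.8 and 65.9 in replicates 2 and 3, which bears on every comparison that uses that group. Both of these higher libraries were the only females of their groups by X- and Y-linked transcripts, so level and sex coincide there. In control and Llgl cKO, females (109, 123 and 120 CPM) and males (130, 122 and 112 CPM) overlapped.

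**Figure D1:**
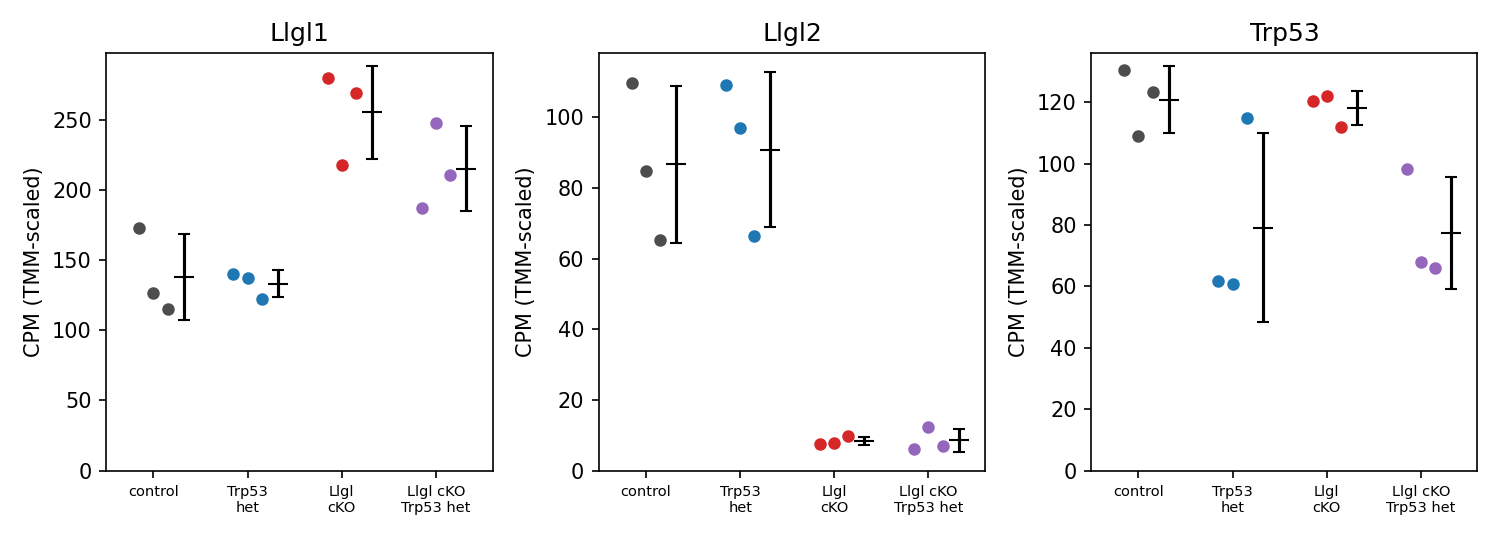
TMM-scaled CPM of Llgl1, Llgl2 and Trp53 in each of 12 libraries (points), with the mean and SD of each group of 3 beside them. Llgl2 is below 15 CPM in each library of both Llgl cKO groups, and Trp53 in the library labelled Trp53 het 3 lies at 115 CPM, at the control level.

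The comparison of Llgl cKO with control addressed the Llgl cKO genotype where Trp53 is intact. Several genes that controls expressed strongly were close to absent, and whether strain background differs between these groups is not known from the labels. Skint9, Skint4 and Skint3, neighbouring genes of the Skint family of immunoglobulin-superfamily genes expressed in skin and thymus, fell from 144 ± 70.7, 29.7 ± 11.6 and 62.9 ± 32.2 CPM (SD, n = 3) to 0, 0 and 0.0243 ± 0.0421. Skint9 was at least 2102-fold lower and Skint4 at least 414-fold lower. The ratio for Skint3, with 1 count in Llgl cKO, was 2765 (495.7 to 109261). Stfa1, a stefin-family inhibitor of cysteine proteases, fell from 205 ± 119 to 1.70 ± 0.440 CPM, and Eno1b, an enolase gene, fell from 20.6 ± 1.57 to 0.105 ± 0.0926 CPM. Among genes that rose, Enpp1, an ectonucleotidase that generates pyrophosphate, went from 9.89 ± 3.46 to 56.7 ± 26.4 CPM (log2 change 2.54). The log2 change was 0.93 for Mgat5, an N-glycan branching enzyme, 0.91 for Dera, a deoxyribose-phosphate aldolase, and 4.25 for the pseudogene Tdpx-ps1. Catsperg2, a gene of a sperm calcium channel complex, was 66.5 times higher (11.6 to 2656), from 1 count in control to 2.33 ± 1.64 CPM in Llgl cKO.

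In that comparison 33 genes were called by edgeR, 13 higher and 20 lower (adjusted p for the named genes from 0.00016 to 0.025), against 115 by DESeq2. Of the 33, 11 were pseudogenes. No member of the hair shaft and inner root sheath list was called (0 of 26, also 0 adjusted over the list alone), although 24 members were lower, with a median of -1.34 (camera adjusted p = 1.3e-07; adjusted p = 0.81 with an estimated correlation). The 11 T cell markers were all lower, with a median of -1.91, 0 called and 3 called adjusted over the list alone (adjusted p = 2.3e-07; 0.42 with an estimated correlation). Hair follicle progenitor and signal genes had a median of 0.44, with 16 of 21 higher, 0 called and 2 adjusted over the list alone (adjusted p = 9.9e-05; 0.42 with an estimated correlation). All 30 genes of G2 and M phase were higher, with a median of 0.50 and 0 called (adjusted p = 1.3e-07; 0.81 with an estimated correlation). Relative to the mean of 12 libraries, control 3 stood at 0.82 on this list, above the Llgl cKO libraries (0.30 to 0.36). Adipocyte markers had a median of -1.88 (adjusted p = 0.041; 0.42 with an estimated correlation), fibroblast markers 0.35 (0.0063; 0.65) and mitochondrial transcripts, a measure of RNA quality, 0.21 (0.040; 0.81), with 0 called in each. These calls were lost in 7, 1 and 3 of the 12 fits that left out a single library. Of 40 lists, 7 passed upward and 5 downward with the preset correlation and 0 with an estimated correlation. By edgeR 920 genes had an unadjusted p below 0.05, where chance gives 729. That number was 587 without control 2 and 589 without Llgl cKO 1, both below the chance value, and 1788 without control 3. Leaving out control 2 gave 15 calls and leaving out Llgl cKO 1 gave 19. The calls of Catsperg2, Tdpx-ps1, Enpp1 and Mgat5 were each lost without control 2, and some of them also without control 1, control 3, Llgl cKO 1, Llgl cKO 2, Llgl cKO 3 or Trp53 het 2 (adjusted p up to 0.167 over the alternatives). That of Dera was lost only when the fit held only the groups compared, and that of Catsperg2 was also lost with the replicate block. Without control 3 and Trp53 het 3 there were 413 calls, 238 higher and 175 lower.

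Epidermis with both changes had lower hair shaft and sebaceous gland transcripts than control, and close to no Skint3, Skint4 or Skint9. In the hair shaft and inner root sheath list 18 of 26 genes fell and 0 rose, with a median of -4.14. Krt33b, a hair keratin, fell from 31.2 ± 21.4 to 0.451 ± 0.563 CPM (SD, n = 3; log2 change -6.04) and Krt82, a hair cuticle keratin, from 17.8 ± 9.39 to 0.752 ± 0.596 (-4.52). Sebaceous gland genes fell in 3 of 14 cases, with a median of -1.41. Awat2, a wax synthase, changed by -2.03 and Soat1, a cholesterol acyltransferase, by -1.56. Skint3 was at least 846-fold lower, Skint9 lower by a ratio of 5792 (1039 to 228805) and Skint4 by a ratio of 1142 (204 to 45144). Pde2a, a cyclic nucleotide phosphodiesterase, rose by 2.24 on the log2 scale, and levels at the mitochondrial transfer RNA genes mt-Tt and mt-Tl1 rose by 2.74 and 2.42. In libraries of polyadenylated RNA such reads need not come from mature transfer RNA. Counts at these genes were low in controls 1 to 3, at 1, 10 and 6 for mt-Tt and 4, 17 and 10 for mt-Tl1.

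The count in that comparison was 182 genes by edgeR, 50 higher and 132 lower, against 627 by DESeq2. Krtap4-1, a keratin-associated protein gene, was lower by a ratio of 262 (72.1 to 2170) and Upp1, a uridine phosphorylase, by 173 (30.6 to 6883). Catsperg2 was higher by 62.4 (10.9 to 2497) and Tdpx-ps1 by 4.40 on the log2 scale. Adjusted over the list alone, 25 hair shaft genes were lower and 1 higher, and 7 sebaceous genes were lower. Camera gave adjusted p of 2.1e-27 for the hair shaft list and 2.3e-06 for the sebaceous list. Both lost the call with an estimated correlation (adjusted p = 0.32 for each), and fry gave adjusted p of 0.021 and 0.026. G2 and M phase genes were higher in 30 of 30 cases with a median of 0.91 and 0 called (camera adjusted p = 4.4e-09; 0.72 with an estimated correlation). Relative to the mean of 12 libraries, controls ran from -1.48 to 0.82, and control 3, the highest, lay inside the Llgl cKO Trp53 het range (0.49 to 0.85). Cholesterol synthesis genes had a median of -0.32 with 0 of 21 called (adjusted p = 0.0013; 0.72 with an estimated correlation), a call lost without control 3. Markers of other cell types moved as well. The 3 adipocyte markers had a median of -4.22 with 0 called (adjusted p = 0.0074; 0.32 with an estimated correlation) and the 11 T cell markers -1.34 with 0 called (0.00038; 0.63). The 10 fibroblast markers had a median of 0.57 with 1 called (0.0014; 0.52). Mitochondrial transcripts, which track RNA quality, were higher in 8 of 8 cases with a median of 0.55 and 0 called (0.0013; 0.63), a call lost without control 1. Of 40 lists, 6 passed upward and 5 downward. Single libraries moved the count. It was 31 without control 1, 25 without control 2 and 351 without control 3. It was 43 without Trp53 het 2, 37 without Llgl cKO Trp53 het 2 and 27 without Llgl cKO Trp53 het 3. With the replicate block it was 347, and without control 3 and Trp53 het 3 it was 1139, 536 higher and 603 lower. The balance was also close to even without control 2 (12 higher, 13 lower), Trp53 het 2 (21 and 22), Llgl cKO Trp53 het 2 (19 and 18) or Llgl cKO Trp53 het 3 (14 and 13), so it depends on the libraries used. The calls of Krt33b, Krt82, Awat2, Soat1, Krtap4-1, Upp1, Catsperg2 and mt-Tt were each lost without control 1, control 2, Llgl cKO Trp53 het 2 or Llgl cKO Trp53 het 3 (adjusted p up to 0.196 over the alternatives). Some of them were also lost without control 3, Trp53 het 1, Trp53 het 2, Llgl cKO 1, Llgl cKO 3 or Llgl cKO Trp53 het 1, and mt-Tl1 was lost without control 1 or Llgl cKO Trp53 het 3. A fit of only the groups compared lost all of these, Pde2a and Tdpx-ps1, except Catsperg2. Those of Skint3, Skint9, Skint4 and Llgl2 held in every alternative run.

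Set against Trp53 het, which addresses the Llgl cKO genotype in Trp53 heterozygotes, Llgl cKO Trp53 het epidermis again had lower hair shaft and sebaceous transcripts. Hair shaft and inner root sheath genes fell in 18 of 26 cases, with a median of -4.04. Tchh, which encodes trichohyalin of the inner root sheath, fell from 1326 ± 613 to 68.3 ± 29.3 CPM (SD, n = 3; log2 change -4.28) and Krt82 by 4.51 on the log2 scale. Sebaceous gland genes fell in 6 of 14 cases with a median of -1.51, among them Soat1 (56.0 ± 9.35 to 15.6 ± 4.26 CPM) and Cidea, a lipid droplet protein (18.4 ± 5.06 to 5.37 ± 1.94 CPM). Of the hair follicle progenitor and signal genes, 3 of 21 rose, including the ligand genes Bmp2 (log2 change 1.10) and Wnt10b (0.56). Krt13, a keratin of internal stratified epithelia, rose from 0.409 ± 0.229 to 2.35 ± 0.919 CPM, and Hddc3 and Ccdc80, an extracellular matrix gene, rose by 2.24 and 2.19 on the log2 scale.

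For that comparison edgeR called 198 genes, 64 higher and 134 lower, and DESeq2 called 704. Skint3 was at least 802-fold lower, and the ratios were 5275 (946.2 to 208385) for Skint9, 1221 (219 to 48281) for Skint4, 235 (64.6 to 1946) for Krtap4-1 and 171 (30.3 to 6817) for Upp1, all lower. Catsperg2 was higher by a ratio of 63.9 (11.1 to 2556) and Tdpx-ps1 by 5.06 on the log2 scale. Adjusted over the list alone, 25 hair shaft genes were lower and 1 higher, 8 sebaceous genes were lower and 4 progenitor genes were higher. Camera adjusted p was 6.2e-26 for the hair shaft list, 7.9e-08 for the sebaceous list and 0.066 for the progenitor list. With an estimated correlation the adjusted p was 0.34, 0.28 and 0.68. Adipocyte markers had a median of -4.01 with 0 of 3 called (adjusted p = 0.0092; 0.28 with an estimated correlation) and T cell markers -1.92 with 0 of 11 called (0.00033; 0.64). Fibroblast markers had a median of 0.48 with 1 of 10 called (0.036; 0.68) and mitochondrial transcripts 0.35 with 0 of 8 called (0.031; 0.68), and each of these latter calls was lost in 3 fits that left out a single library. Of 40 lists, 6 passed upward and 5 downward in this comparison. The library labelled Trp53 het 3 is part of the baseline here: without it the count was 322, and the same count was reached without control 3. Counts were 89 without control 1, 50 without control 2, 24 without Trp53 het 1 and 32 without Trp53 het 2, each with more lower than higher calls. They were 44 without Llgl cKO Trp53 het 2 (21 higher, 23 lower) and 24 without Llgl cKO Trp53 het 3 (11 and 13), a balance close to even. The count was 376 with the replicate block, and without control 3 and Trp53 het 3 it was 1088 with a near-even balance, 532 higher and 556 lower. Among the named genes, Skint3, Skint9, Skint4 and Llgl2 held in every alternative. The others each lost the call without Trp53 het 1, and all but Tdpx-ps1 also without Trp53 het 2, Llgl cKO Trp53 het 2 or Llgl cKO Trp53 het 3 (adjusted p up to 0.176 over the alternatives). Some were lost as well without control 1, control 2, any Llgl cKO library, Llgl cKO Trp53 het 1 or, for Krt13, the library labelled Trp53 het 3. The call of Krt13 was also lost with the replicate block.

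Averaged over both Trp53 genotypes, the Llgl cKO genotype went with lower hair shaft, sebaceous, T cell and adipocyte transcripts and with higher levels of several follicle signalling genes. Of 26 hair shaft and inner root sheath genes 20 fell and 0 rose, with a median of -2.77. Tchh was at 1425 ± 973 CPM in control, 1326 ± 613 in Trp53 het, 462 ± 334 in Llgl cKO and 68.3 ± 29.3 in Llgl cKO Trp53 het (SD, n = 3), and Krt33b changed by -3.82 on the log2 scale. Sebaceous gland genes fell in 5 of 14 cases with a mean log2 change of -0.81 over the list, Awat2 changing by -1.55 and Soat1 by -1.07. In Llgl cKO against control the sebaceous list was not called (median -0.31, 0 of 14 called, camera adjusted p = 0.30). Relative to the mean of 12 libraries it stood at 0.29 ± 0.30 in control, 0.045 ± 0.274 in Llgl cKO, 0.47 ± 0.33 in Trp53 het and -0.81 ± 0.20 in Llgl cKO Trp53 het (SD, n = 3). The hair shaft list was uneven too, at 0.034 in control 3 and 0.48 in Trp53 het 3 against 1.12 in Llgl cKO 2. By contrast 4 of 21 hair follicle progenitor and signal genes rose and 0 fell. These were Bmp2 (0.96), Lgr6 (0.61), an R-spondin receptor of stem cells in the upper follicle, Lef1 (0.92) and Wnt10b (0.44). Wnt pathway targets rose in 3 of 13 cases, Sp5 by 1.63, Lef1 by 0.92 and Nkd1 by 0.84.

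T cell markers fell in 3 of 11 cases with a median of -1.89, among them Il2rb, an interleukin receptor chain (-2.44), and Cd3g, of the T cell receptor complex (-2.32), while 0 of 17 markers of macrophages and Langerhans cells were called (median -0.10, camera adjusted p = 0.55). Adipocyte markers fell in 2 of 3 cases, with log2 changes of -2.94 for Fabp4 and -3.83 for Retn. Control 3 and Trp53 het 3 stood at the Llgl cKO level for both, with 0.81 and 1.81 CPM of Fabp4 against 0.76 to 2.26 in Llgl cKO, and 0.97 and 0.68 CPM of Retn against 0.35 to 1.92. The T cell list was likewise at -0.43 in Trp53 het 3, relative to the mean of 12 libraries, inside the range of Llgl cKO (-1.48 to -0.40). Fibroblast markers rose in 2 of 10, Sparc by 0.94 and Fbln1 by 0.53, whereas the collagen gene Col1a1 of the same list was at -0.90 and was not called. Among stress keratins and alarmins Stfa1 fell by 6.85, while Sprr2d, a cornified envelope precursor gene, rose by 3.07 and Serpinb2 by 0.80. In the group of unfolded protein and integrated stress response genes, Hspa5, the endoplasmic reticulum chaperone BiP, fell by 0.66 and Vldlr, a lipoprotein receptor, rose by 0.56. YAP and TAZ targets had Ccdc80 higher by 1.39 and Igfbp3 at -1.82, with 0 of the other 22 called. Camera called none of these 3 lists: adjusted p was 0.86 for stress keratins and alarmins, whose median of 0.12 and mean of -0.15 differ in sign, 0.097 for the stress response genes and 0.47 for the YAP and TAZ targets.

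This average effect had 485 called genes by edgeR, 172 higher and 313 lower, and 1016 by DESeq2. Of the 485, 316 had changed at least 2-fold and 41 were pseudogenes. Beyond the genes above, the ratios were 11551 (2073 to 456302) for Skint9, 5163 (926.2 to 203993) for Skint3 and 2469 (443 to 97562) for Skint4, all lower, and 163 (44.9 to 1352) for Nr1h5, a nuclear receptor gene, and 65.3 (17.8 to 543.7) for Catsperg2, both higher. Nr1h5 had 0, 74 and 0 counts in Llgl cKO 1 to 3 and 92, 91 and 148 in Llgl cKO Trp53 het 1 to 3. Eno1b changed by -7.18, Tdpx-ps1 by 4.66 and Pcna-ps2 by 4.27 on the log2 scale. Camera gave 7 lists up and 6 down of 40. The adjusted p was 1.5e-20 for hair shaft, 7.0e-05 for sebaceous gland, 0.0060 for progenitors, 0.0030 for Wnt targets, 2.5e-06 for T cells, 0.0070 for adipocytes and 0.011 for fibroblasts. With an estimated correlation the adjusted p was 0.44, 0.44, 0.57, 0.49, 0.49, 0.44 and 0.61 in that order, and 0 of the 40 lists passed. Fry gave adjusted p of 0.022, 0.028, 0.055, 0.051, 0.051, 0.020 and 0.072. Adjusted over the list alone, the counts were 24 lower and 1 higher for hair shaft, 8 lower for sebaceous gland, 5 higher for progenitors, 3 higher and 1 lower for Wnt targets, 9 lower for T cells, 3 lower for adipocytes and 4 higher for fibroblasts.

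Some lists share members: Lef1, Dkk4 and Lgr5 stand in both the progenitor and the Wnt list, and Thy1 in both the fibroblast and the T cell list. The proliferation lists moved with the groups, the 30 G2 and M phase genes having a median of 0.62 with 0 called (camera adjusted p = 4.4e-09; 0.63 with an estimated correlation), and the 28 S phase genes a median of 0.25 (adjusted p = 0.0045; 0.80 with an estimated correlation). Their levels were uneven within the groups with intact Llgl. Relative to the mean of 12 libraries, the G2 and M phase list stood at -1.48, -1.06 and 0.82 on the log2 scale in controls 1 to 3 and at -1.24, -1.14 and 1.04 in Trp53 het 1 to 3. It stood between 0.30 and 0.85 in the 6 Llgl cKO libraries. Mitochondrial transcripts, a measure of RNA quality, had a median of 0.29 with 8 of 8 higher and 0 called (adjusted p = 0.011; 0.63 with an estimated correlation). Interferon-stimulated genes had a median of -0.35 (adjusted p = 0.042; 0.77 with an estimated correlation), genes of glycolysis and the hypoxia response -0.17 (0.039; 0.63) and those of the epithelial-mesenchymal transition 0.19 (0.042; 0.44). The S phase call was lost without control 1, and that of mitochondrial transcripts without control 1 or Llgl cKO Trp53 het 3. The calls of the interferon, glycolysis and transition lists were lost in 8, 6 and 4 of the 12 fits that left out a single library. Those of the interferon and transition lists were also lost with the replicate block, and that of the transition list with sex as a term.

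Counts for the average Llgl effect were 311 without control 1, 164 without control 2 and 187 without Llgl cKO 1. They were 240 without Trp53 het 1, 225 without Trp53 het 2, 191 without Llgl cKO Trp53 het 2 and 203 without Llgl cKO Trp53 het 3, and 2334 without control 3 and Trp53 het 3, 1185 higher and 1149 lower, so that the excess of lower calls was absent there. The calls of Llgl1, Llgl2, Skint3, Skint4, Skint9, Stfa1, Eno1b, Catsperg2, Tdpx-ps1, Bmp2, Lgr6, Sp5, Sparc, Krt33b and Awat2 held in every alternative, and that of Tchh was lost only without the low-count filter. Those of Soat1, Lef1, Igfbp3, Ccdc80, Hspa5, Vldlr, Fbln1, Fabp4, Retn, Il2rb, Cd3g, Sprr2d, Pcna-ps2 and Nr1h5 were lost in 1 to 10 of the 12 fits that left out a single library, each of the 12 ending at least 1 call and most often control 2, Trp53 het 1 or Llgl cKO Trp53 het 2 (adjusted p up to 0.117 with Nr1h5 aside, and up to 1 for Nr1h5).

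**Figure D2:**
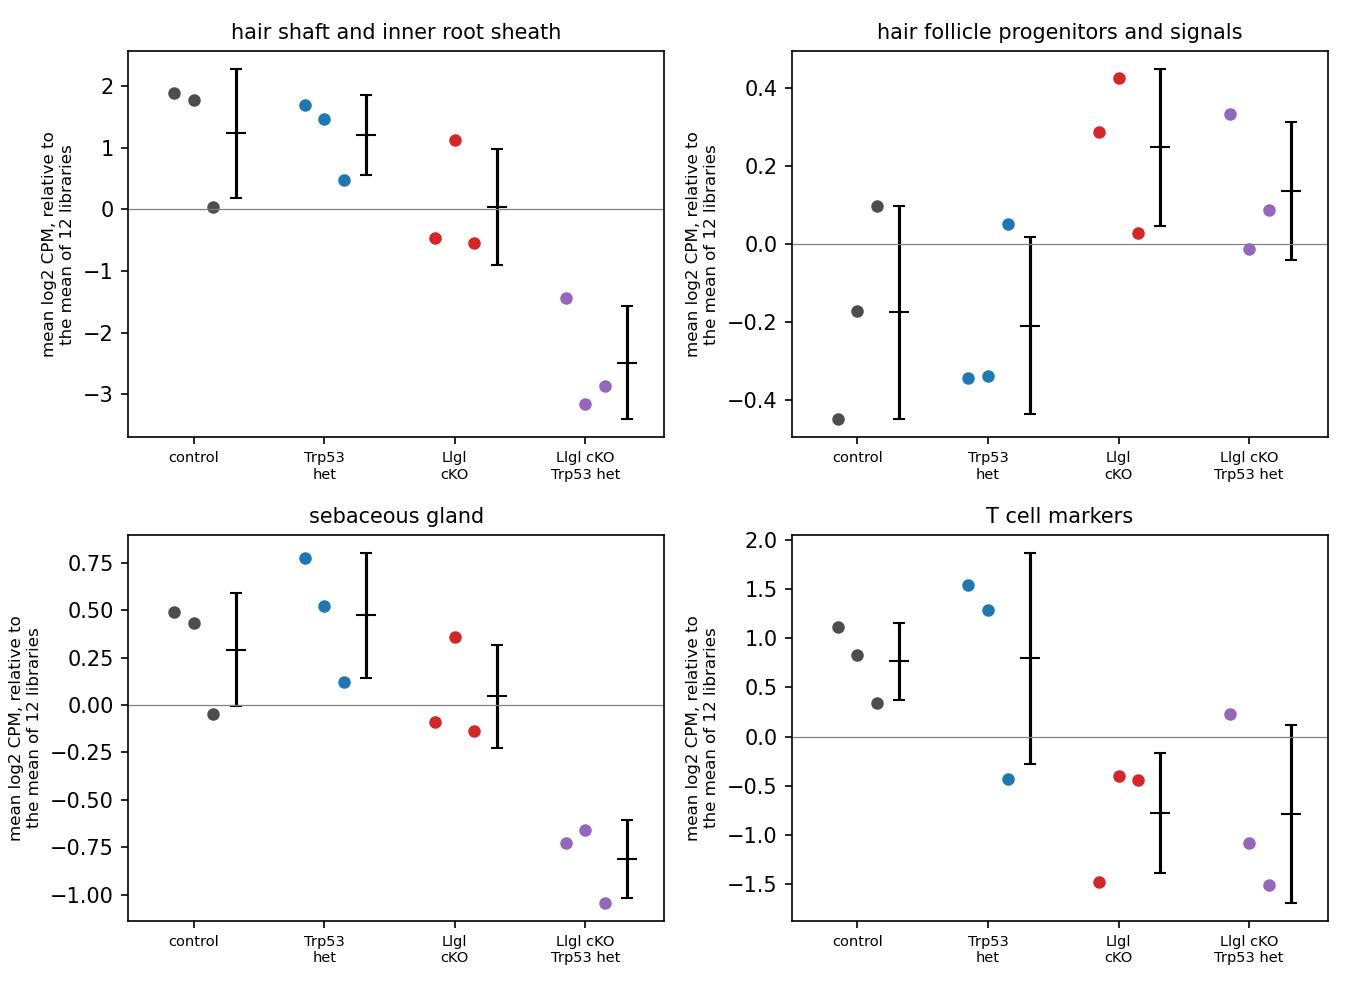
Mean log2 CPM of 4 gene lists in each of 12 libraries, relative to the mean over all libraries (points), with mean and SD per group of 3. Hair shaft genes lie between -3.16 and -1.44 in Llgl cKO Trp53 het and between 0.034 and 1.90 in control, whereas progenitor genes lie between -0.45 and 0.43 in all libraries.

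The Llgl effects in Trp53 wild-type and Trp53 heterozygous epidermis were alike in direction for most genes. Across 14582 genes, which are not independent replicates, the log2 fold changes of these comparisons had a Pearson correlation of 0.758 and a Spearman correlation of 0.563. The comparisons share no library, but their baselines are not independent: same-numbered control and Trp53 het libraries deviate alike from their group means (correlations 0.62, 0.21 and 0.82). Part of the agreement may come from this, and the average Llgl effect likewise counts these libraries as independent. The sign was the same for 69.5% of the 14582 genes. All 33 genes called in the wild-type background had the same sign in the heterozygous one, and 195 of the 198 called there had the same sign in the wild type. Both comparisons called 12 genes higher and 18 lower, and 0 in opposite directions.

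**Figure D3:**
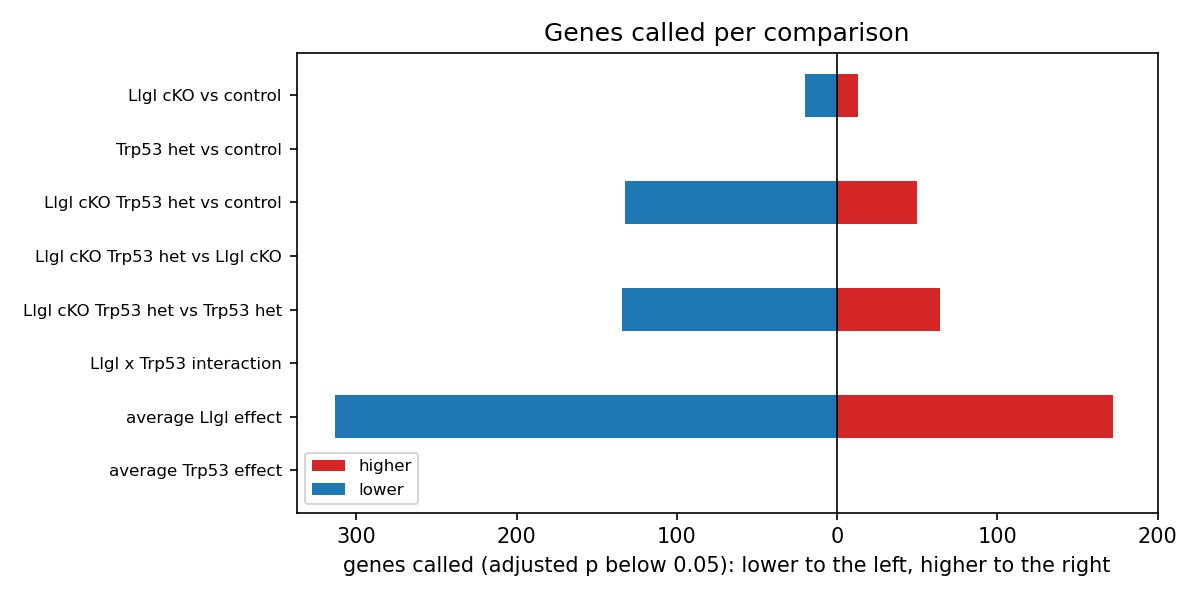
Genes called by edgeR at an adjusted p below 0.05 in each of 8 comparisons, lower to the left and higher to the right. The average Llgl effect has 172 higher and 313 lower, and the comparisons of Trp53 genotypes and the interaction have 0.

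In Trp53 het against control, with intact Llgl1 and Llgl2, changes in p53 target genes were not detected. Trp53 itself, at -0.61 on the log2 scale, was not called in this comparison either. The lack of calls therefore does not show that p53 targets are unaffected. None of 33 p53 targets was called (0 also adjusted over the list alone), with a median of -0.11. Ephx1, an epoxide hydrolase, was at 34.8 ± 1.96 CPM in Trp53 het and 42.1 ± 10.7 in control (SD, n = 3), and Rps27l at 56.9 ± 4.15 and 62.1 ± 2.44. The late cornified envelope genes were lower in 19 of 19 cases with 0 called (median -0.32, camera adjusted p = 0.0010; 0.97 with an estimated correlation), a call that was lost without control 1, control 2 or the library labelled Trp53 het 3 (median -0.0055 without the last). By edgeR 0 genes were called, by DESeq2 0, and 63 had an unadjusted p below 0.05 against 729 expected by chance. The last count was 243 without control 3 and 252 without Trp53 het 3, and 40 to 252 over the alternatives. The library labelled Trp53 het 3 carried Trp53 at the control level, which bears on every comparison that uses this group.

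On the Llgl cKO background, hair shaft and sebaceous transcripts were lower as lists in Trp53 heterozygotes, with 0 single genes called by edgeR over all genes. Hair shaft and inner root sheath genes had a median of -2.74 with 25 of 26 lower, 0 called and 25 adjusted over the list alone, and sebaceous genes a median of -0.77 with 0 called and 5 adjusted over the list alone. Camera adjusted p was 3.0e-33 and 1.2e-09. With an estimated correlation both were lost (adjusted p = 0.30 for each), and fry gave 0.17 for each. Cholesterol synthesis genes were lower in 20 of 21 cases with a median of -0.35 (adjusted p = 3.5e-07; 0.58 with an estimated correlation). Lower medians were also seen for markers of melanocytes (-0.37; adjusted p = 0.020, and 0.58 with an estimated correlation), mural cells (-2.32; 0.037 and 0.33) and dermal papilla (-0.99; 0.0497 and 0.58). Mitochondrial transcripts were higher, with a median of 0.27 (0.045 and 0.67). None of these genes was called (0), and the list calls were lost in 2, 3, 7 and 6 of the 12 fits that left out a single library. The dermal papilla call was also lost with the replicate block. Of 40 lists, 4 passed upward and 8 downward. The p53 targets had a median of 0.03 with 0 of 33 called. The smallest p were those of Sulf2, an extracellular sulfatase (-0.37 on the log2 scale), and Dcxr, a xylulose reductase (0.41). By edgeR 0 genes were called, with 747 at an unadjusted p below 0.05 (407 without Llgl cKO 2 to 1049 without Llgl cKO Trp53 het 1), and DESeq2 called 48, 4 higher and 44 lower.

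Averaged over both Llgl genotypes, the Trp53 effect had 0 genes called by edgeR and 0 by DESeq2, with 316 at an unadjusted p below 0.05 (168 without Llgl cKO 2 to 575 without Llgl cKO Trp53 het 1). Hair shaft genes had a median of -1.45 with 0 called and 25 adjusted over the list alone (camera adjusted p = 2.0e-29; 0.66 with an estimated correlation). With intact Llgl the median was -0.12 (adjusted p = 0.94). The interaction, which tests the difference between backgrounds, called 0 genes, and its call for this list was lost with an estimated correlation (0.40) and by fry (0.55). Relative to the mean of 12 libraries the list stood at 1.24 ± 1.04 in control and 1.22 ± 0.65 in Trp53 het, against 0.034 ± 0.944 in Llgl cKO and -2.49 ± 0.92 in Llgl cKO Trp53 het (SD, n = 3). Of 40 lists, 4 passed upward and 6 downward, and 0 passed with an estimated correlation. Among them were mitochondrial transcripts, a measure of RNA quality (camera adjusted p = 0.0051), and markers of fibroblasts (0.0082), dermal papilla (0.047) and melanocytes (0.047). Their calls were lost in 2, 4, 8 and 8 of the 12 fits that left out a single library. Those of dermal papilla and melanocytes were also lost with the replicate block. The p53 targets had a median of -0.01, Sulf2 being at -0.13 and Eda2r, a receptor of the tumour necrosis factor family, at -0.56 on the log2 scale. Across genes, the Trp53 effects in the 2 Llgl genotypes had a Pearson correlation of 0.041 and a Spearman correlation of -0.029. The Pearson correlation ran from -0.092 to 0.143 when single libraries were left out and was negative without control 1, control 2, the library labelled Trp53 het 3, Llgl cKO Trp53 het 2 or Llgl cKO Trp53 het 3. These averages include the library labelled Trp53 het 3.

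Whether the Llgl effect differed with Trp53 genotype was tested as an interaction, and no single gene passed. By edgeR 0 genes were called, by DESeq2 0, and 428 had an unadjusted p below 0.05 (243 without Llgl cKO 2 to 619 without Trp53 het 3). The hair shaft and inner root sheath list was lower in Trp53 heterozygotes beyond the effect in wild types, with a median of -2.68, 25 of 26 lower, 0 called and 21 adjusted over the list alone (camera adjusted p = 1.2e-24; 0.40 with an estimated correlation; fry adjusted p = 0.55). Sebaceous gland genes had a median of -0.91 with 0 called and 3 adjusted over the list alone (9.9e-10; 0.33 with an estimated correlation), and cholesterol synthesis genes -0.28 with 0 called (0.00019; 0.69 with an estimated correlation), a call lost without Llgl cKO 3. The p53 targets had a median of 0.09 with 0 of 33 called, Sulf2 being at -0.47 and Rps27l at 0.31. In the Llgl comparisons the p53 targets were likewise not called, with medians of -0.06 for Llgl cKO against control, -0.06 for Llgl cKO Trp53 het against control, 0.06 against Trp53 het and -0.0043 on average. Aen, a p53-induced nuclease, was at -0.49, -0.40 and, on average, -0.39 (adjusted p = 0.079). Plk2 was at 0.32 in Llgl cKO, Dcxr at 0.53 and 0.69 in Llgl cKO Trp53 het against control and Trp53 het, and Apaf1 at 0.37 against Trp53 het.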

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

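The list results and the splits of the libraries were planned; the tests of the large changes and of the Trp53 label under the other observations were chosen only after the results were seen, and the tests of the hair shaft pattern were set before their results were seen.

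Hair shaft and inner root sheath genes drew attention because the interaction tests whether the Llgl effect differs between Trp53 genotypes. The median of the Llgl effect in Trp53 heterozygotes minus that in wild types was -2.68 on the log2 scale, with 0 of 26 genes called (camera adjusted p = 1.2e-24; 0.40 with an estimated correlation). Sebaceous gland genes gave -0.91 with 0 of 14 called (9.9e-10; 0.33 with an estimated correlation). Cholesterol synthesis genes gave -0.28 with 0 of 21 called (0.00019; 0.69 with an estimated correlation). The group with the lowest hair shaft levels, Llgl cKO Trp53 het, ranged from -3.16 to -1.44 relative to the mean of the 12 libraries, and the other groups from -0.55 to 1.90.

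Lower hair shaft and inner root sheath transcripts in the average Llgl effect (median -2.77) were set against technical explanations. A smaller share of hair follicle cells in the samples would lower progenitor genes too, but their median was 0.41. The lowest of 21 members, Msx2, picked after its value was seen, was at -0.39. The call of the progenitor list was lost with an estimated correlation (camera adjusted p = 0.0060; 0.57). Its levels overlapped, reaching 0.097 in control and -0.012 in Llgl cKO Trp53 het. The list showed no fall, but it is not a direct measure of the share of follicle cells. Without control 3 and Trp53 het 3, which stood apart, the median of the hair shaft list was -3.14. These libraries had the lowest hair shaft levels of their groups (0.034 and 0.48). Leaving them out would deepen the fall in any case, so this does not test their part in it. Control 3 stood at the mean of the Llgl cKO group (0.034). With sex as a term the median was -2.80. What stays open includes a smaller number of differentiated shaft and sheath cells with progenitors retained, and an effect of the Llgl genotype itself. A difference in developmental timing between litters, which the labels do not give, stays open too. No test here separates these. Other differences in the make-up of the samples were not tested. Adipocyte markers ranked the groups as the hair shaft list did (0.98 in control, 0.94 in Trp53 het, -0.37 in Llgl cKO and -1.55 in Llgl cKO Trp53 het). Fibroblast markers ranked them in reverse (-0.37, -0.07, 0.14 and 0.31). With an estimated correlation between the genes of the hair shaft list, the camera adjusted p was 0.44.

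Refitting with other splits of the same libraries tested whether the counts exceed those of arbitrary groupings. For the pairwise comparisons 10 splits exist, so the share can never be under 0.1. The real count was 33 for Llgl cKO against control, 182 for Llgl cKO Trp53 het against control and 198 against Trp53 het, with a highest other count of 0 in each, and 1 of 10 splits, the real one, reached it. For Llgl cKO Trp53 het against Llgl cKO the real count was 0 and the highest other 3, and for Trp53 het against control 0 and 343. A count of 0 is reached by any split, so these comparisons are not tested in this way. The split with 343 calls set control 1, Trp53 het 1 and Trp53 het 2 against control 2, control 3 and Trp53 het 3. By the sex read from transcripts, the former were all male and the latter all female. This split parted 1 same-numbered pair where the real split parts 3. It points to a structure of these 6 samples other than Trp53 genotype. Sex matches that structure exactly, but whether it accounts for the 343 calls was not tested. Each of the other splits had 0 calls.

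For the average Llgl effect 2 of 100 splits reached the real count of 485, a share under 0.05, which would exclude chance only if the libraries were independent. The correlation between same-numbered control and Trp53 het libraries puts that in doubt. The other one called 1398 genes, several times the real count, and points to a structure of the samples: it set control 1, control 2, Llgl cKO 1, Trp53 het 1, Trp53 het 2 and Llgl cKO Trp53 het 2 against the rest, which hold control 3 and Trp53 het 3. For the interaction and the average Trp53 effect, with 0 calls in each, 40 of 40 splits reach that count by necessity, so the splits say nothing about chance there. The highest other count was 485 for the interaction, from the split that exchanges the Llgl labels within a single Trp53 genotype and so gives the average Llgl effect, and 1 for the average Trp53 effect.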

How the results depend on the processing

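The 2 alternatives that leave out chosen libraries, control 3 with Trp53 het 3 and the library with the most Trp53 in each Trp53 heterozygous group, were added after seeing the data. The other alternatives were planned. Changes of scaling, of the low-count filter and the sex term kept the total of called genes within 1.5 times its value in every comparison. Counts by direction moved further in places. Without the filter 13 higher calls became 21 in Llgl cKO against control, 132 lower calls became 87 in Llgl cKO Trp53 het against control, and 313 became 202 in the average Llgl effect. With the sex term the 132 became 205. No scaling moved the median of all genes by over 0.1 on the log2 scale. Of 73 called results for named genes 29 held in every alternative and 0 reversed. The DESeq2 fit lost 0 of them, the fit without control 2 lost 35 and the fits of only the groups compared lost 18 of 43. Of 73 list calls 0 held with an estimated correlation and 10 by fry, and in the other settings between 51 and 72 held. Where a library is left out, the remaining libraries of its group are assumed to vary like the other groups. Depth limits genes near the floor, and 3 mice per group limit the detection of 2-fold changes. The cause was not tested for any change below. Fewer libraries leave fewer residual degrees of freedom, which does not account for the fits with fewer libraries that gave more calls.

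For Llgl cKO against control (33 genes), DESeq2 called 115 and the fit without control 3 and Trp53 het 3 called 413; leaving out single libraries gave 15 to 42. For Llgl cKO Trp53 het against control (182), DESeq2 called 627, the fit of only the groups compared 49, the fit with the replicate block 347 and the fit without control 3 and Trp53 het 3 called 1139; leave-one-out fits gave 25 to 351. For Llgl cKO Trp53 het against Trp53 het (198), the corresponding counts were 704, 117, 376 with the block and 1088, and 24 to 322. For the average Llgl effect (485), 316 genes had changed at least 2-fold, DESeq2 called 1016 and the fit without control 3 and Trp53 het 3 called 2334, with 164 to 697 when single libraries were left out. For Trp53 het against control (0), 1 gene was called without control 3 and Trp53 het 3, and leave-one-out fits gave 0 to 1. For Llgl cKO Trp53 het against Llgl cKO (0), DESeq2 called 48, the fit without control 3 and Trp53 het 3 called 1, and leave-one-out fits gave 0 to 1. For the average Trp53 effect (0), 1 gene was called without the libraries with the most Trp53 and 2 without control 3 and Trp53 het 3. The interaction had 0 calls in every alternative run. Correlations of effects ran from 0.643 to 0.779 for Llgl and from -0.092 to 0.143 for Trp53 over the leave-one-out fits. The replicate block changed no call between control and Trp53 het. There each same-numbered pair correlated above 0.1, which does not establish pairing by number. In the other pairs of groups same-numbered libraries did not all correlate above 0.1. The block gave 31 calls for Llgl cKO against control, 664 for the average Llgl effect and 0 for the other 3 counts of 0.

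Changes of sign were seen for targeted genes that were not called, for lists whose calls were lost with an estimated correlation and for the correlation of the Trp53 effects. With sex as a term the log2 change became 0.071 for Trp53 in Llgl cKO against control, -0.11 for Llgl2 in Trp53 het against control, -0.00078 for Llgl2 in Llgl cKO Trp53 het against Llgl cKO, 0.11 for Llgl2 and the interaction, 0.027 for Trp53 and the average Llgl effect, and -0.054 for Llgl2 and the average Trp53 effect. With the replicate block it became -0.0020 for Llgl2 in Llgl cKO Trp53 het against Llgl cKO and 0.0013 for Trp53 and the interaction, and with upper-quartile scaling the latter became 0.0082. Without the libraries with the most Trp53 it became 0.0078 for Llgl1 in Trp53 het against control, and for Trp53 0.12 in Llgl cKO Trp53 het against Trp53 het, 0.16 in the interaction and 0.046 in the average Llgl effect. Without control 3 and Trp53 het 3 the last 3 became 0.33, 0.35 and 0.16. For lists, without the libraries with the most Trp53 the median became -0.0057 for late cornified envelope genes in Trp53 het against control, where the camera direction turned, 0.042 for tight junction genes and -0.24 for G2 and M phase genes in the average Trp53 effect.

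Leave-one-out ranges that crossed zero, for Trp53, were -0.10 to 0.025 in Llgl cKO against control, -0.25 to 0.33 in Llgl cKO Trp53 het against Trp53 het, -0.21 to 0.37 in the interaction and -0.14 to 0.15 in the average Llgl effect. Those for Llgl2 were -0.10 to 0.28 in Trp53 het against control, -0.34 to 0.22 in Llgl cKO Trp53 het against Llgl cKO, -0.42 to 0.15 in the interaction and -0.13 to 0.15 in the average Trp53 effect, and that for Llgl1 was -0.17 to 0.15 in Trp53 het against control. For lists, S phase genes in Llgl cKO against control ran from -0.11 (without control 1) to 0.97. Late cornified envelope genes in Trp53 het against control ran from -0.61 to 0.12 with -0.0055 without Trp53 het 3, and G2 and M phase genes in the average Trp53 effect from -0.31 (without Trp53 het 3) to 0.82.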

Other observations

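Keratin-associated protein genes, Skint genes and mitochondrial transfer RNAs were singled out as families after their values were seen. Keratin-associated protein genes, which encode matrix proteins of the hair shaft, fell in 36 of 49 cases in the average Llgl effect (median -4.17, 48 lower, and 36 fell under each other scaling). In Llgl cKO against control 0 of the 49 were called, although 49 were lower (median -2.62), and 10 fell in Llgl cKO Trp53 het against control. Of 11 Skint genes 6 fell and 0 rose in the average Llgl effect, with the same counts under both other scalings. Skint6 stood between 1.82 and 3.52 CPM in the 6 Llgl cKO libraries and between 25.2 and 71.6 in the other 6. Skint1, known for its part in the selection of dendritic epidermal T cells, stood between 15.5 and 26.0 CPM and between 22.7 and 37.7. BC117090, a stefin gene close to Stfa1, was also singled out after its values were seen and moved the other way. It stood between 4.43 and 9.49 CPM in the 6 libraries with intact Llgl and between 75.7 and 175 in the 6 Llgl cKO libraries. Levels at all 3 tested mitochondrial transfer RNA genes rose in the average Llgl effect (median 1.65), although mt-Tt and mt-Tl1 had at most 10 and 17 counts in any control library.

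Large changes in the average Llgl effect, of at least 4-fold, numbered 202 genes, of which 77 lay in or near the keratin and keratin-associated gene arrays and 125 elsewhere, 39 higher and 86 lower. The following tests were chosen after these genes had been seen. Strain DNA carried along with the floxed alleles is argued against as the whole cause, since 8 of the 125 (6.4%, exact 95% interval 2.80 to 12.2) lay within 20 Mb of Llgl1 or Llgl2, against 6.06% of other tested genes. Setting the keratin arrays aside removed linked genes: 37 of those 77 lay within 20 Mb, as the chromosome 11 array is near Llgl2. Over all 202 the share was 45 (22.3%, exact 95% interval 16.7 to 28.6) against 6.32% of other tested genes, so linked DNA stays open for a part. Of the 40 array genes that were not linked, 39 were lower. Strain differences at unlinked loci cannot be told apart from other causes: 25 of 117 unlinked genes (21.4%) had another such gene within 1 Mb, inside the range of random sets (8.55 to 26.5%, median 17.1%). Reads shared with near-identical copies stay open for a part. Of the 125, 31 were pseudogenes (24.8% against 2.40% of other tested genes, Fisher odds ratio 13.4, exact 95% interval 8.52 to 20.7), 25 of them higher. The genes that these pseudogenes copy were not examined, so this excess does not separate shared reads from strain differences. Skint3, Skint4, Skint9, Stfa1, Eno1b and Catsperg2 are among the unlinked genes, so strain differences and an effect of the Llgl genotype both stay open for them. Reads shared with near-identical copies were not examined for these genes and stay open too. For Stfa1, the nearby stefin gene BC117090 moved the other way in the same libraries. An effect of the Llgl genotype remains open for the others too. The 125 also include Rpph1 and Rmrp, annotated as ribozyme genes and picked after their values were seen. Both were lower (-4.55 and -3.90 on the log2 scale), whereas the mitochondrial transfer RNA gene mt-Tt was higher (2.09). Differences between groups in library preparation or in carry-over of such RNA were not tested.

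Trp53 in the library labelled Trp53 het 3 (115 CPM) prompted a check for exchanged labels, also chosen after the value was seen. An exchange with a control would leave a control at the level of the other Trp53 het libraries, but the lowest control stood 47.2 CPM above the higher of those, against a control SD of 10.98 CPM. A single wrong label or incomplete recombination stays open. The library was also the only female of its group, so its Trp53 level cannot be told apart from sex within that group. Of the 66 pairs of libraries, control 3 and Trp53 het 3 differed least, with a chi-square per degree of freedom of 2.97 and the highest correlation of log2 CPM (0.993).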
